A study of Mus musculus with 11 samples.

How the data were processed

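Genome positions of HIV integration were analysed for 11 libraries from LEDGF-deficient mouse embryonic fibroblasts, 1 for each fused protein: the NELF subunits NELFE, NELFCD, NELFB and NELFA, SPT5, the Integrator subunits INTS11, INTS9 and INTS3, and the SOSS subunits NABP2, NABP1 and INIP. Per the labels' protocols, plasmids were electroporated, cells were infected 24 hours later and grown for 3 more days, and junctions between the viral LTR and the genome were amplified by linker-mediated nested PCR and sequenced as read pairs on a GAIIx or HiSeq instrument. Reads were mapped to mm9, per the submitters' processing notes. Aligner, read filters and the number of reads required per junction are not given in the sources used here.

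The deposited values are other than counts or signal: per the file headers, each entry is a 0-based genome position of the first base beyond the LTR with its strand. The 873534 entries were collapsed to 831994 distinct combinations of chromosome, position and strand, since amplified copies of an integration and different linker ends repeat a position. The read name of an entry is followed by 2 numbers whose meaning the headers do not state. The first was never below 2 and was treated as a number of reads, and the second as a fragment length. Read names also gave the instrument, flow cell and lane. Repeat runs of a protein were counted as 1 library. All sites lay on chromosomes 1 to 19 and X. Coordinates are 1-based on mm9, and genes came from an annotation of the same assembly with 37252 genes on these chromosomes, of which 22350 are protein-coding and 32044 are not pseudogenes.

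Families were fixed from the known complexes before the data were examined: NELF (4 libraries), SOSS (4), INTS9 with INTS11, and SPT5. The gene lists, the tests of similarity and of genes and regions, and part of the alternatives were fixed then too, and other tests were added after the data had been seen. For NELF against Integrator, the 4 NELF libraries were set against the 6 of SOSS, INTS9 and INTS11, and SPT5 is given beside them. Values are means ± SD over the libraries of a side unless SE is named.

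Libraries were thinned at random to 18753 sites, the size of the smallest, for clustering, overlap and similarity, with 10 thinnings averaged for similarity. Clustering is the share of sites with another site of the same library within 1 kb. Overlap is the share of sites with a site of another library within 1 kb, divided by its mean over 20 circular shifts along each chromosome. Similarity is the Spearman correlation of counts over windows of 100 kb, tested with exact one-sided permutation tests over assignments of the family labels. Shares of sites carry exact binomial (Clopper-Pearson) intervals and gene list densities exact Poisson intervals, both at 95%.

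Gene features were shares of sites inside protein-coding genes and around their starts and ends, beside the share of the genome. Profiles used bins of 200 bases. Gene lists were 12 lists of names or name patterns with 5 kb on each side of each gene, given as the fold over uniform density. The pattern for spliceosomal snRNA genes matched 0 gene names, which left 11 lists, and copies of these genes were taken later by another rule given with their values. Differences in features, profiles and lists were tested with exact two-sided permutation tests over all 210 splits of 10 libraries into 4 and 6, for lists on log2 of the fold plus 0.1. These tests were added after the data had been seen, and the 1-kb window around starts, meant as an alternative to 5 kb, was given its own test and first place for the same reason. Adjusted p-values are Benjamini-Hochberg values within each family of tests.

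Genes with 5 kb on each side and regions of 1 Mb were compared with limma (trend and robust settings) on log2 of sites per 100000 sites plus a pseudocount of 1. They needed a mean of at least 10 sites per library, which left 1139 genes and 2221 regions, and passed at a Benjamini-Hochberg rate of 0.05. Named genes followed a fixed rule: the 10 genes with the most sites per 100000 over the 11 libraries; of the genes that passed, the 10 largest folds in each direction with every NELF library on 1 side of the Integrator mean; and 2 to 4 members of each list with the most sites. Of the genes that were lower in NELF and met the rule, 2 are not described here. Other genes named are said to have been chosen after their values were seen.

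The comparison was tested on simulated counts with the real means and library sizes and a coefficient of variation of 0.3. Of 50 genes changed 4-fold upward 98% were recovered, and of 50 changed 2-fold 18%. For changes to 0.25 and 0.5 the shares were 66% and 8%, with 0 false calls among 95. For regions the shares were 96% and 38% upward and 82% and 26% downward, with 2 false calls among 123. Spread in the data varied, and at the gene Plec it was 52.7 ± 7.63 sites per 100000 in NELF and 58.7 ± 32.1 in Integrator. The simulated shares and false calls may thus not hold where the spread is larger. On simulated sites, unrelated libraries had an overlap of 0.973 times chance, and 10% of planted shared sites gave 10.0%. The family test was tried on random similarity values, not on sites, and 8% of 50 such unrelated sets had a family p under 0.05.

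Alternatives covered merging sites within 10 bases, other distances, windows, similarity measures, pseudocounts, filters, voom weights, quantile normalisation, thinning and leaving out each library. Alternatives added after the data had been seen were sites with a first number of at least 10, all annotated genes, a common distribution of local GC content (200 bases around the site, bins of 4%, at least 20 sites per bin), sites with 35 unique genome bases, and 1 site per 100 bases. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used. The symmetry of base composition around sites was centred on base 2 downstream for the plus strand and base 3 for the minus strand in all 11 libraries, so the strands follow conventions that differ by 1 base. Identical positions were compared within a strand.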

Results

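HIV integration sites were mapped in mouse embryonic fibroblasts without LEDGF, the chromatin protein that normally tethers the viral integrase. In each of 11 libraries a different protein carried the integrase-binding domain of LEDGF. This design is meant to lead viral DNA to places where that protein meets chromatin. How many sites of a library were led there by the fused protein was not tested here. The question was where subunits of the Integrator complex, which cleaves nascent transcripts, and their partners in transcription meet the genome. INTS9 and INTS11 belong to the cleavage module of Integrator. INTS3 and INIP form SOSS complexes with either NABP1 or NABP2, which are alternative subunits, and these complexes join Integrator through INTS3. The 4 proteins are called SOSS here, and the 6 libraries of SOSS, INTS9 and INTS11 are called the Integrator libraries here. NELFA, NELFB, NELFCD and NELFE are the subunits of NELF, which holds RNA polymerase II in a pause near the start of genes, and SPT5 is the large subunit of DSIF, the partner of NELF in pausing.

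The 11 libraries held 831994 distinct sites, each a chromosome, position and strand, with a median of 41265 per library. INTS9 gave 197069 sites, NABP1 188432, INTS3 96318, NABP2 88204 and SPT5 82038. The smaller libraries were NELFCD with 41265, INTS11 with 33939, NELFB with 30960, NELFA with 30109, INIP with 24907 and NELFE with 18753. Between 49.5% and 50.4% of a library's sites lay on the plus strand. Each protein had 1 library, so the subunits of a complex, or of related complexes in SOSS, stood in for replicates and every p-value measures the spread between fused subunits, part of which may be technical. Intervals around single libraries cover counting error only, and no integration without a fused protein was analysed here, so values are set against uniform positions. All 4 NELF libraries came from a flow cell that held no other library, so no value within a batch can be had for NELF against Integrator, and family and flow cell cannot be told apart in that comparison. SPT5 was also alone on its flow cell, while SOSS libraries came from several flow cells, and INTS9 shared one of them with NABP1 and NABP2.

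SPT5 and NELFB sites lay most densely together, and INIP and INTS9 sites least so. With every library thinned to 18753 sites, 22.4% of SPT5 sites (95% exact binomial interval 21.8 to 23.04) and 22.4% of NELFB sites (21.8 to 22.98) had another site of the same library within 1 kb. The share was 18.8% for NELFCD (18.3 to 19.4), 18.2% for NELFA (17.7 to 18.8) and 11.7% for NELFE (11.2 to 12.1). Among the Integrator libraries it was 13.3% for NABP2 (12.8 to 13.8), 9.35% for NABP1 (8.94 to 9.78) and 8.25% for INTS3 (7.86 to 8.65). INTS11 had 5.34% (5.02 to 5.67), INTS9 4.27% (3.99 to 4.57) and INIP 3.89% (3.62 to 4.17). Uniform positions of the same number gave 1.54% (1.37 to 1.73). The shares were not tested between families.

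Chromosomes 11 and 19 were rich in sites of every protein, and chromosome X was poor in them. Relative to a library's own density over the genome, chromosome 11 held 1.65 ± 0.166 times as many sites per Mb (SD, n = 11 libraries; range 1.37 to 1.93) and chromosome 19 held 1.496 ± 0.129 times. Chromosomes 15 and 17 followed with 1.40 ± 0.128 and 1.36 ± 0.131. The ratio was 0.507 ± 0.0868 on chromosome X, 0.642 ± 0.0611 on chromosome 14 and 0.720 ± 0.0735 on chromosome 12.

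Sites of NELF libraries lay near those of other NELF libraries and of SPT5 more often than Integrator sites lay near each other. Overlap was counted within 1 kb, as the fold over the mean of 20 circular shifts of the second library along each chromosome. The 6 pairs within NELF had a mean fold of 11.8 (range 9.63 to 14.5), with 16.4% of sites shared, and the 4 pairs of NELF with SPT5 had 12.4 (9.69 to 14.2), with 16.6% shared. NELFB with NELFCD reached 14.5. The 24 pairs of a NELF with an Integrator library had a mean fold of 5.51 (3.07 to 7.83), with 7.78% shared, and the 6 pairs of SPT5 with an Integrator library had 6.22 (3.65 to 8.25). Within SOSS the 6 pairs had a mean fold of 4.90 (2.93 to 7.37), the 8 pairs of SOSS with INTS9 or INTS11 had 3.65, and INTS9 with INTS11 had 3.08. Over all 55 pairs the mean fold was 6.398 and the lowest 2.47.

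Sets of libraries were compared in these overlaps with 6 exact one-sided permutation tests on the log2 folds. The 4 NELF libraries overlapped each other more than nearly all other sets of 4 libraries did, with a set as high in 4 of 330 (exact p = 0.0121, adjusted p = 0.0364). NELF together with SPT5 had the highest mean of all 462 sets of their size (exact p = 0.00216, the smallest these sets allow, adjusted p = 0.013). SOSS did not stand apart (exact p = 0.77, adjusted p = 0.996), nor did INTS9 with INTS11 (exact p = 0.927, adjusted p = 0.996) or the 6 Integrator libraries (exact p = 0.996, adjusted p = 0.996). Over all 4 family labels together the exact p was 0.0513 (adjusted p = 0.103). These tests, and the sets of NELF with SPT5 and of the 6 Integrator libraries, were chosen after the overlaps had been seen. Circular shifts do not keep a preference for gene starts, so libraries rich in sites there can overlap more whatever their complex. The tests therefore cannot tell membership of a complex from a shared preference for starts.

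**Figure D1:**
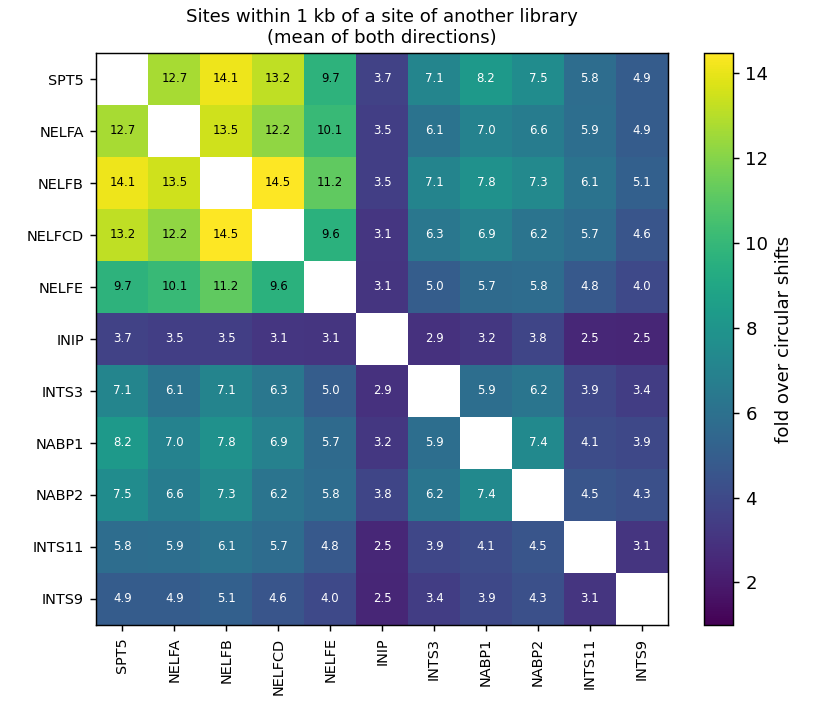
Fold of shared sites within 1 kb over circular shifts for each pair of the 11 libraries, all thinned to 18753 sites. NELF and SPT5 pairs hold the highest folds, up to 14.5 for NELFB with NELFCD.

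On a coarser scale, correlations of site counts did not separate the families. NABP1 with NABP2 had the highest Spearman correlation of site counts over 25654 windows of 100 kb, at 0.394, and INTS3 followed with NABP2 at 0.374 and with NABP1 at 0.368. INIP with INTS11 had the lowest, at 0.183. Mean correlations within families exceeded those between families by 0.0185, which was within the spread over all assignments of the labels (exact one-sided permutation p = 0.0934, adjusted p = 0.374 over 4 tests). Within NELF the mean was 0.321 (exact p = 0.276, adjusted p = 0.412) and within SOSS it was 0.316 (exact p = 0.309, adjusted p = 0.412), where a set of 4 libraries could have reached 0.00303. INTS9 with INTS11 had 0.226 (exact p = 0.945, adjusted p = 0.945). Without INIP the 3 other SOSS libraries had a mean of 0.378 (exact p = 0.00833). The correlations are across windows, which are not independent replicates.

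Sites of the NELF and SPT5 libraries lay near starts of protein-coding genes far more often than sites of the Integrator libraries. NELF subunits placed 19.6% ± 4.31 of their sites (SD, n = 4 libraries) within 1 kb of a start, and Integrator subunits 6.65% ± 1.58 (n = 6), against 1.65% of the genome (exact two-sided permutation p = 0.0048, the smallest of 210 splits; adjusted p = 0.0143 over 6 tests). NELFB had the highest share of NELF, 22.9% (95% exact binomial interval 22.4 to 23.4), and NELFE the lowest, 13.4% (12.9 to 13.9). SPT5 lay beside them with 22.6% (22.3 to 22.9). Among the Integrator libraries NABP1 had 8.50% (8.38 to 8.63), INTS11 7.35% (7.07 to 7.63), INTS3 7.27% (7.11 to 7.44) and INTS9 6.84% (6.73 to 6.95). NABP2 had 6.10% (5.95 to 6.26) and INIP 3.86% (3.62 to 4.11). All 4 NELF libraries lay above all 6 Integrator libraries.

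**Figure D2:**
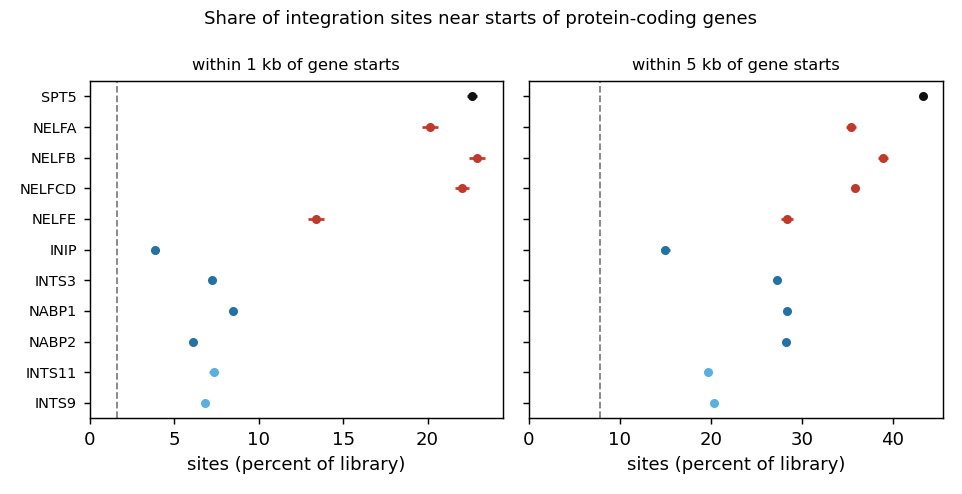
Percent of each library's sites within 1 kb of the start of a protein-coding gene, with 95% exact binomial intervals; the dashed line marks the 1.65% of the genome. NELF libraries lie between 13.4% and 22.9%, SPT5 at 22.6%, and Integrator libraries between 3.86% and 8.50%.

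Within 5 kb of starts the difference was smaller beside the spread, with 34.6% ± 4.43 for NELF and 23.1% ± 5.58 for Integrator (exact permutation p = 0.019, adjusted p = 0.0286). SPT5 had 43.4% there, and the genome share was 7.85%. Within 1 kb of gene ends NELF had 4.54% ± 0.357 and Integrator 3.12% ± 0.547 (exact permutation p = 0.0048, adjusted p = 0.0143), with 5.396% for SPT5 and 1.67% of the genome. Within 5 kb of ends the shares were 17.6% ± 0.921 and 13.5% ± 1.92 (exact permutation p = 0.0095, adjusted p = 0.019), with 21.2% for SPT5. Histone genes are short, so sites there count at starts and ends alike. With the sites within 5 kb of the 71 histone genes left out, a choice made after the data had been seen, the shares within 1 kb of ends were 3.44% ± 0.118 and 3.003% ± 0.507 (exact permutation p = 0.138, adjusted p = 0.207 over 6 tests). Within 5 kb of ends they were 16.04% ± 1.04 and 13.3% ± 1.86 (exact permutation p = 0.0286, adjusted p = 0.0762), and within 5 kb of starts 33.4% ± 4.76 and 22.98% ± 5.52 (exact permutation p = 0.0381, adjusted p = 0.0762). None of these 3 passed after adjustment, while within 1 kb of starts the shares were 18.96% ± 4.69 and 6.56% ± 1.54 (exact permutation p = 0.0048, adjusted p = 0.0286). Inside genes NELF had 52.9% ± 0.795 and Integrator 56.8% ± 5.80, which did not differ beyond the spread (exact permutation p = 0.252, adjusted p = 0.303). SPT5 had 59.6% inside genes, and 38.8% of the genome lies there. Farther than 5 kb from genes the shares were 31.4% ± 1.46 and 33.3% ± 6.56 (exact permutation p = 0.595, adjusted p = 0.595), with 25.1% for SPT5 and 55.3% of the genome.

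NELF and SPT5 had higher peaks close to gene starts than the Integrator subunits. In bins of 200 bases the highest density of NELFB, NELFCD and NELFE lay 200 to 400 bases downstream of the start, with 23.5-fold, 21.6-fold and 11.2-fold the uniform density. NELFA had its highest bin, at 16.8-fold, between −400 and −200 bases, and SPT5 had 19.9-fold in the first 200 bases. Integrator peaks were lower and lay farther downstream: 7.10-fold for NABP1 at 600 to 800 bases, 6.49-fold for INTS11 and 6.31-fold for INTS3 at 800 to 1000 bases. INTS9 had 5.10-fold at 400 to 600 bases, NABP2 6.46-fold at 1400 to 1600 bases and INIP 3.22-fold at 800 to 1000 bases.

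**Figure D3:**
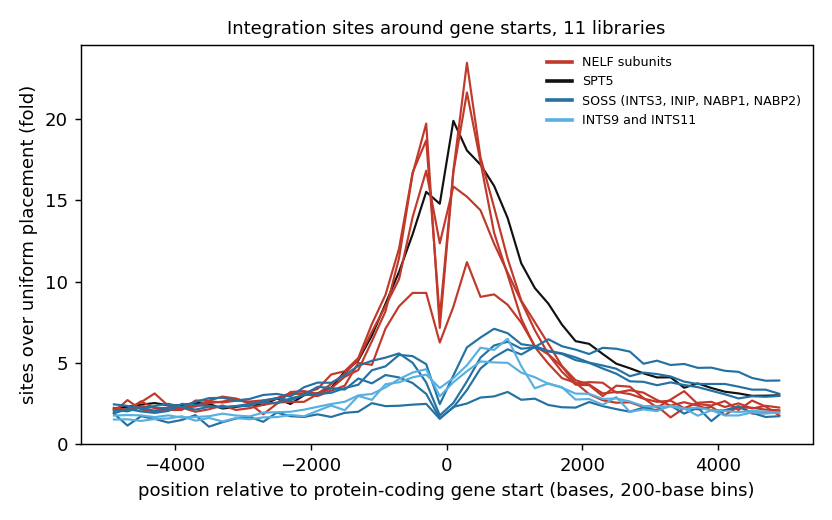
Site density around starts of protein-coding genes in bins of 200 bases, as the fold over uniform positions, for each library. NELF and SPT5 peak within 400 bases of the start at 11.2-fold to 23.5-fold, and the Integrator libraries peak downstream at 3.22-fold to 7.10-fold.

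Summaries of these profiles were compared in 10 exact two-sided permutation tests over 210 splits. In the 1 kb downstream of starts NELF density was 13.9 ± 3.33 and Integrator density 4.69 ± 1.14 times uniform (exact p = 0.0048, adjusted p = 0.0095), with 17.0 for SPT5. In the 1 kb upstream the values were 11.5 ± 2.28 and 3.72 ± 0.839 (exact p = 0.0048, adjusted p = 0.0095), with 12.5 for SPT5. From 1 to 5 kb downstream NELF and Integrator did not differ beyond the spread, with 3.38 ± 0.249 and 3.52 ± 1.22 (exact p = 0.833, adjusted p = 0.833), and SPT5 had 5.15. Density within 1 kb of starts was also divided by that at 1 to 5 kb, with upstream and downstream sides in each. This ratio was 4.003 ± 0.915 for NELF and 1.504 ± 0.424 for Integrator (exact p = 0.0048, adjusted p = 0.0095), with 3.62 for SPT5. Past gene ends, in the 1 kb downstream, NELF had 2.99 ± 0.196 and Integrator 2.01 ± 0.355 (exact p = 0.0048, adjusted p = 0.0095), with 3.62 for SPT5. Without the sites around histone genes the values past ends were 2.25 ± 0.0638 and 1.93 ± 0.315 (exact p = 0.0714, adjusted p = 0.102 over 10 tests). The ratio of density near ends to that farther away did not differ between the families beyond the spread, with 1.01 ± 0.113 and 0.986 ± 0.039 (exact p = 0.752, adjusted p = 0.833). Without the sites around histone genes NELF lay lower, with 0.8945 ± 0.0736 and 0.974 ± 0.0375 (exact p = 0.0619, adjusted p = 0.102), which did not pass either. NELFE had the highest ratio, 1.159, with its highest bin, at 3.88-fold, 200 to 400 bases past ends. Without the sites around histone genes its ratio was 1.001, below 1.037 for NABP2, and its highest bin, at 2.79-fold, lay at 1400 to 1600 bases.

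Histone genes, whose transcripts end without a poly(A) tail, stood out among the gene lists fixed for this comparison. NELF density over the 71 replication-dependent histone genes was 120.4 ± 28.9 times uniform, that of the Integrator libraries 14.7 ± 6.96 and that of SPT5 35.9 (95% exact Poisson interval 32.7 to 39.3). NELFE had the highest value, 157 (143 to 172), and NELFCD the lowest of NELF, 86.8 (79.8 to 94.3). NABP2 led the Integrator libraries with 22.7 (20.3 to 25.4), and INTS9 had 7.996 (7.03 to 9.06). INIP was lowest with 4.65 (2.75 to 7.35), from 18 sites. The exact two-sided permutation p was 0.0048, the smallest that 210 splits give. With 11 lists the smallest adjusted p is 0.0524, which this list reached, so no list could pass 0.05 after adjustment.

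**Figure D4:**
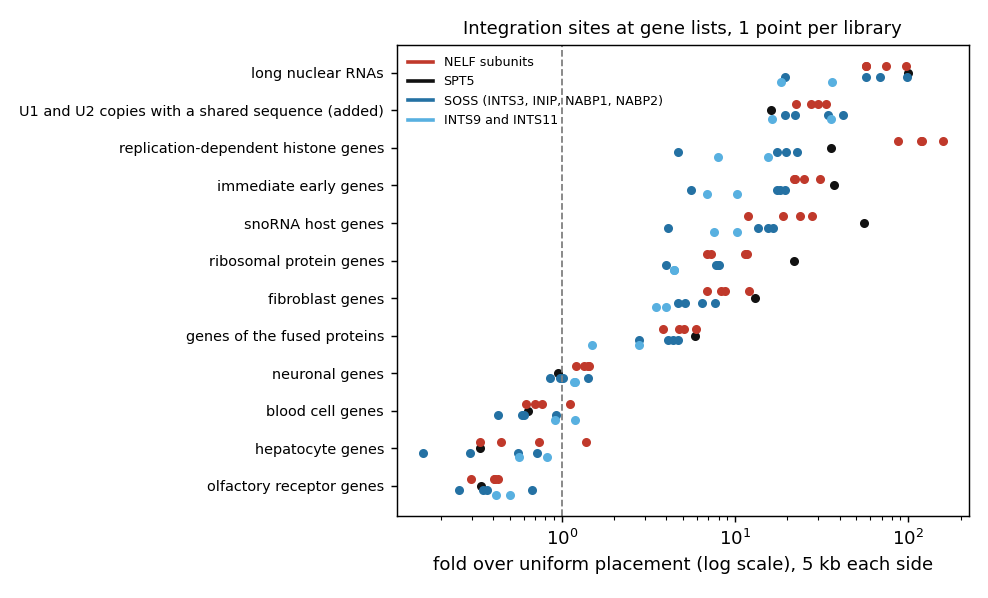
Site density in each fixed gene list with 5 kb on each side, as the fold over uniform positions on a log axis, for each library. Histone genes range from 4.65-fold in INIP to 157-fold in NELFE, and olfactory receptor genes lie below uniform.

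In SPT5 the long nuclear RNAs and the snoRNA host genes had higher densities than the histone genes, and in each Integrator library the long nuclear RNAs did too. The SPT5 density over Malat1 and Neat1 was 99.2 (84.0 to 116), against 71.2 ± 18.9 for NELF and 49.5 ± 30.9 for Integrator (exact permutation p = 0.186, adjusted p = 0.255). Over 9 snoRNA host genes SPT5 had 55.2 (48.2 to 63.0), NELF 20.5 ± 6.73 and Integrator 11.2 ± 4.86 (exact permutation p = 0.0619, adjusted p = 0.12). Over 79 ribosomal protein genes SPT5 had 21.8 (20.3 to 23.3), NELF 9.30 ± 2.60 and Integrator 6.09 ± 1.99 (exact permutation p = 0.0714, adjusted p = 0.12). Over 22 immediate early genes the values were 37.4 (33.8 to 41.3), 24.9 ± 4.22 and 12.9 ± 6.10 (exact permutation p = 0.0333, adjusted p = 0.12). Over 24 fibroblast genes they were 12.95 (11.7 to 14.2), 8.94 ± 2.15 and 5.22 ± 1.57 (exact permutation p = 0.0143, adjusted p = 0.0786). SPT5, with 1 library, was not tested against the families.

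Genes of other tissues lay near or below uniform density in NELF and Integrator alike. Olfactory receptor genes (1251) had 0.385 ± 0.0592 in NELF, 0.426 ± 0.146 in Integrator and 0.341 in SPT5 (exact permutation p = 0.7, adjusted p = 0.77). Neuronal genes (14) had 1.35 ± 0.103, 1.10 ± 0.196 and 0.952 (exact permutation p = 0.0476, adjusted p = 0.12). Blood cell genes (9) had 0.798 ± 0.221, 0.772 ± 0.282 and 0.632 (exact permutation p = 0.776, adjusted p = 0.776). Hepatocyte genes (8) had 0.723 ± 0.467, 0.516 ± 0.2495 and 0.337, from 29 sites in all (exact permutation p = 0.438, adjusted p = 0.535). The genes of the fused proteins themselves (11) had 4.88 ± 0.864, 3.36 ± 1.22 and 5.86 (exact permutation p = 0.0762, adjusted p = 0.12).

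Among single list members, sites are given per 100000 sites of a library, over the gene with 5 kb on each side. Hist1h2bb (chromosome 13, 23838603 to 23839071) had 143.5 ± 36.7 in NELF, 12.8 ± 7.85 in Integrator and 34.1 in SPT5. Hist1h3i had 129 ± 37.9 and 12.5 ± 7.67, and Hist1h4a 116 ± 48.9 and 15.5 ± 8.69. Neat1, the scaffold RNA of paraspeckles, had 84.8 ± 24.1 in NELF, 47.8 ± 29.4 in Integrator and 113 in SPT5, and Malat1 had 48.3 ± 13.6, 44.7 ± 28.5 and 71.9. Snhg9, whose window also covers Rps2, had 51.2 in SPT5 beside 16.2 ± 5.26 and 12.5 ± 9.83, and Snhg1 had 41.4 beside 13.7 ± 6.14 and 8.997 ± 3.26. Snhg3 had 36.6 in SPT5, 15.5 ± 4.87 in NELF and 10.3 ± 6.06 in Integrator. The AP-1 gene Junb had 37.2 ± 14.5 in NELF and 19.2 ± 10.2 in Integrator, Fosl1 28.5 ± 13.6 and 24.9 ± 15.4, and Ier2 35.6 ± 15.1 and 13.8 ± 8.72. Zfp36, which codes for a factor of mRNA decay, had 26.1 ± 4.06, 11.2 ± 7.89 and 52.4 in SPT5.

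Cald1, which codes for the actin-binding protein caldesmon, had 22.3 ± 13.5 sites per 100000 in NELF and 41.9 ± 16.8 in Integrator, while Cyr61, a matrix-associated growth regulator, had 57.5 ± 19.6 and 15.2 ± 10.03. Col5a1 had 15.3 ± 6.30 and 26.7 ± 18.4, and Sparc 26.7 ± 13.1 and 14.3 ± 4.18. Rpl23a had 17.0 ± 8.002 and 13.7 ± 8.62, and Rpl10a 21.04 ± 2.83 and 9.72 ± 6.04. Olfr56 had 15.2 ± 8.44 and 5.05 ± 3.27 and Olfr1423 2.24 ± 1.55 and 2.20 ± 1.44, in that order. Syt1 had 17.99 ± 3.17 and 20.6 ± 8.97, and Rbfox3 16.2 ± 7.42 and 11.6 ± 6.71. Ptprc had 3.05 ± 2.67 and 2.27 ± 2.09, and Itgam 3.05 ± 2.67 and 2.37 ± 2.31. Apob had 1.33 ± 2.67 and 0.608 ± 0.697, from 8 sites in all, and Fgb had 5 sites in all. Of the genes of the fused proteins, Cpsf3l, the gene of INTS11, had 6.67 ± 4.50 and 10.6 ± 5.74, and Obfc2a, the gene of NABP1, had 16.5 ± 2.89, 5.14 ± 2.83 and 30.5 in SPT5.

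The genes with the most sites over all libraries were partly long gene models. Gm20388, a model of several Mb on chromosome 8 (122434741 to 126869622), had 507.6 ± 101 sites per 100000 (SD, n = 11), Fgfr2 115 ± 14.2 and Macrod2 59.4 ± 16.8. Tex14 on chromosome 11, whose model spans copies of the U1 snRNA gene, had 119 ± 42.4, with 96.2 ± 10.1 in NELF, 143 ± 44.4 in Integrator and 70.7 in SPT5 (limma adjusted p = 0.252). Neat1 had 67.2 ± 34.2, Hist1h2bb 62.2 ± 68.0, Gm17627 61.0 ± 26.9 and Gm16736 60.7 ± 19.4. Plec, the gene of the cytoskeletal linker plectin, had 59.5 ± 25.6, and Brd2, the gene of a bromodomain protein, had 57.9 ± 29.8.

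Most genes called higher in NELF than in Integrator lay at or beside histone genes, but most of the higher loci lay elsewhere. Of 1139 genes tested with limma, 90 passed a Benjamini-Hochberg rate of 0.05, with 86 higher and 4 lower in NELF, and 257 had an unadjusted p under 0.05. The filter kept 52 of the 71 histone genes, and as it counts sites of all 10 libraries, NELF sites helped genes to pass it. All 52 were higher, with a median log2 fold change of 3.43. Of the 19 left out, 14 had a higher mean in NELF, 2 a lower mean and 3 no sites. The 30 with a mean of at least 10 sites in the Integrator libraries alone were all among the 52. Of the 86 higher genes, 60 had windows that met a histone gene window. The 90 genes fell into 38 loci, and 20 of the 34 higher loci lay away from histone genes. In 88 of the 90 genes every NELF library lay beyond every Integrator library, as in 138 of all 1139 (12.1%), where chance gives 0.952%. The 90 were picked on the same libraries, so their separation is not further support. Windows of neighbouring genes overlap, so the 12.1% counts some sites more than once. With quantile-normalised values 115 genes passed, 85 higher and 30 lower.

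The 10 largest folds all lay in a stretch of chromosome 13. Hist1h4h (23622919 to 23623388) had 95.9 ± 19.03 sites per 100000 in NELF and 5.09 ± 4.11 in Integrator, a log2 fold change of 4.35 ± 0.56 (SE, adjusted p = 4.55e-05, limma), with 30.5 in SPT5. Hist1h1d, a linker histone gene, had 115 ± 42.8 and 6.11 ± 4.40, a log2 fold change of 4.34 ± 0.58 (adjusted p = 6.28e-05, limma). Hist1h4b followed with 4.34 ± 0.79 (adjusted p = 0.000966, limma). Hist1h2be, with the smallest adjusted p of the 10 largest, had 136 ± 33.6 and 9.71 ± 6.62, a log2 fold change of 3.88 ± 0.44 (adjusted p = 1.19e-05, limma). Hist1h2af, Hist1h3g, Hist1h3b and Hist1h4f lay between 3.81 and 4.17 on the log2 scale, as did the lincRNA 4930558J22Rik with 3.94. The lincRNA Gm11335 had 4.28. Windows of neighbouring histone genes overlap, so these values are not independent.

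**Figure D5:**
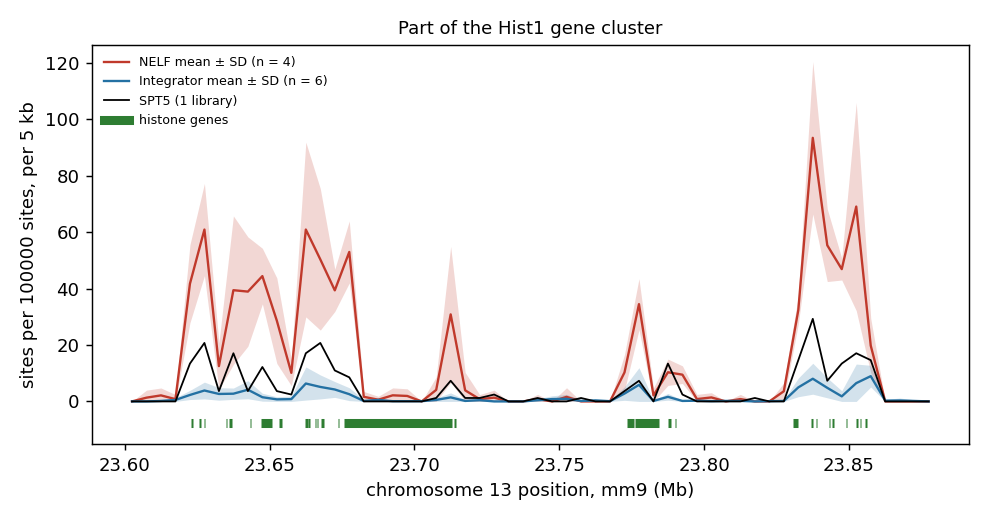
Sites per 100000 in bins of 5 kb across part of the histone cluster on chromosome 13, as the mean ± SD of the 4 NELF and of the 6 Integrator libraries and as the SPT5 value, with 29 histone genes marked. The bin from 23835001 to 23840000 holds 93.4 ± 27.0 NELF and 8.04 ± 5.48 Integrator sites per 100000, and 29.3 for SPT5.

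Among the lists, Cyr61 was higher in NELF over all genes (log2 fold change 2.03 ± 0.45, adjusted p = 0.0055, limma), as 1 of 4 fibroblast genes tested. Adjusted over the list alone, 1 fibroblast gene was higher and 1 lower. None of 6 immediate early genes tested passed over all genes, and 5 were higher adjusted over the list alone, with a median log2 fold change of 1.32. Zfp36 had 1.45 ± 0.51 (adjusted p = 0.0957 over all genes, limma), Ier2 1.73 ± 0.71 (adjusted p = 0.158) and Junb 1.04 ± 0.45 (adjusted p = 0.179). Of the histone genes all 52 also passed adjusted over the list alone. Neat1 and Malat1 (2 tested), the ribosomal protein genes (2), Snhg9 (1) and Syt1 (1) had no call either way of adjusting.

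Genes away from histone genes that were higher in NELF included Flna, Id3 and Pfn1, named here after their values had been seen. Flna, the gene of the actin crosslinker filamin A, had 48.7 ± 10.1 sites per 100000 in NELF, 14.5 ± 6.34 in Integrator and 75.6 in SPT5 (log2 fold change 1.75 ± 0.37, adjusted p = 0.00316, limma). Id3, which codes for an inhibitor of helix-loop-helix factors, had 77.3 ± 30.6, 23.6 ± 17.1 and 39.0 (1.94 ± 0.49, adjusted p = 0.0174, limma). Pfn1, the profilin gene, had 31.1 ± 10.1, 10.9 ± 5.19 and 65.8 (1.53 ± 0.45, adjusted p = 0.0469, limma).

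Luzp1 and a copy of the U1 snRNA gene were among the 4 genes lower in NELF, and the others are not described here. Luzp1, the gene of a leucine zipper protein (chromosome 4, 136025676 to 136110695), had 3.48 ± 4.02 sites per 100000 in NELF, 31.1 ± 16.2 in Integrator and 9.75 in SPT5, a log2 fold change of −3.37 ± 0.69 (adjusted p = 0.00282, limma). The U1 copy (chromosome 3, 96290478 to 96290642) had 9.07 ± 4.14 and 26.4 ± 10.7, a log2 fold change of −1.42 ± 0.41 (adjusted p = 0.0429, limma). Its families overlapped, and at equal library sizes its log2 fold change was −0.24 (adjusted p = 0.938, limma).

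In 1-Mb regions the histone clusters of chromosome 13 led, while the regions with the 10 histone genes of chromosome 3 and with H2afx on chromosome 9 did not pass. Of 2221 regions tested with limma, 10 passed, with 7 higher and 3 lower in NELF, and 248 had an unadjusted p under 0.05. The region of chromosome 13 from 23000001 to 24000000, with 29 histone genes, held 943 ± 242 sites per 100000 in NELF, 116 ± 38.1 in Integrator and 294 in SPT5, a log2 fold change of 3.05 ± 0.31 (adjusted p = 3.91e-08, limma). The region from 21000001 to 22000000, with 18 histone genes, had 2.56 ± 0.25 (adjusted p = 3.91e-08, limma), and the region between them, with 5, had 2.27 ± 0.24 (adjusted p = 8.7e-08, limma). Regions with Hist3 genes beside Trim17 on chromosome 11 and with Hist4h4 on chromosome 6 had 1.72 and 1.63. Regions without histone genes were led by Rb1cc1 on chromosome 1, with 1.40 ± 0.23 (adjusted p = 0.000339, limma), and by Irgm1 on chromosome 11, with 1.197 ± 0.211 (adjusted p = 0.00108, limma). The regions of Luzp1, Zfand3 and Vapa were lower, with log2 fold changes of −1.23, −0.86 and −1.37 (adjusted p = 0.049 each, limma).

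Libraries of different proteins also shared exact positions. Summed over the 55 pairs, 6536 positions and strands occurred in both libraries, where a position found in several pairs counts in each. The mean per base of offset at 1 to 20 bases was 538.6, a ratio of 12.1. Leaving such positions out of the overlaps gave a mean fold of 11.8 within NELF, 12.4 for NELF with SPT5 and 4.87 within SOSS.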

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

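The rule for snRNA gene copies and the values around them were chosen after the data had been seen. INIP lay far above the other 5 Integrator libraries at copies of the U1 and U2 snRNA genes whose sequence is shared by at least 2 copies (14 U1 and 4 U2 copies). Its density within 1 kb of these copies was 128.7 times uniform, and the others had 20.4 to 48.9. In the 1 kb downstream of the copies INIP had 267.9 times uniform, and the others had 11.8 to 67.6. These 2 values are not independent, and they came from 50 groups of values examined for a library far from the others, of which chance singles out about 1 in 20. Of the 47 INIP sites downstream, 45 had genome sequence that is unique over 35 bases, and they lay beside 9 copies, 25 at U1 and 22 at U2, with at most 10 at a copy. No explanation was tested for INIP.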

How the results depend on the processing

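Alternatives with a first number of at least 10, a common GC distribution, all annotated genes, unique sequence or 1 site per 100 bases, the merging of sites for gene features, leaving out sites around histone genes for gene features, and leaving out libraries for gene features, lists and snRNA copies were chosen after the data had been seen; the others were planned. For the results that answer a comparison, 61 values under alternatives that kept all libraries stayed on their side of the threshold or within their spread. Of the others, 8 moved, 1 no longer passed and 1 reversed. Exact permutation tests were judged here by p-values before adjustment. The share within 5 kb of starts without histone sites is therefore among the 61, though it did not pass after adjustment (adjusted p = 0.0762, exact permutation test). With a library left out, 80 stayed and 3 passed a threshold that the full set did not. INTS9 with INTS11 is not among them, because leaving out a library outside the pair cannot change its correlation of 0.226, so its stability was not tested. No paired analysis was possible because each protein has replicate number 1 only, so the groups share fewer than 2 numbers. A minimum of 2 for the first number removed nothing, since no entry lies below it.

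Counting only sites with a first number of at least 10 left 427591 sites, by construction. The mean share of sites with a neighbour, 12.5% within 1 kb, was 3.13% within 100 bases and 34.6% within 10 kb, and the mean overlap of 6.398 was 10.5 within 100 bases and 2.67 within 10 kb, where chance matches change with distance. Identical positions had a ratio of 12.9 to offsets of 5 to 50 bases in place of 12.1, since fewer sites lie farther apart. The excess of correlations within families, 0.0185, was −0.0006 with all sites and no thinning (exact permutation p = 0.494). Its p was 0.0513 to 0.0933 under the other alternatives, and the cause was not tested. The NELF excess within 10 kb of starts was 8.77 percentage points (exact permutation p = 0.0714) in place of 11.5 within 5 kb, and the cause was not tested. Without the sites within 5 kb of histone genes it was 10.5 percentage points within 5 kb of starts (exact permutation p = 0.0381, adjusted p = 0.0762, which no longer passed after adjustment) and 12.4 within 1 kb (exact permutation p = 0.0048, adjusted p = 0.0286). The difference within 1 kb of gene ends fell to 0.441 (exact permutation p = 0.138). With a mean of at least 30 sites, 31 genes remained to be tested with limma and 0 passed, with 8 at an unadjusted p under 0.05, in place of 90 of 1139. With 5-Mb bins 1 of 532 passed, in place of 10 of 2221. Other alternatives gave 71 genes with thinned libraries to 127 without a filter, and quantile-normalised values gave 115, of which 30 were lower in NELF in place of 4.

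With each library left out in turn, the family excess ranged from 0.0108 to 0.0267. It passed 0.05 without INTS9 (0.0267, exact permutation p = 0.0451) and without SPT5 (0.0209, exact permutation p = 0.0279). The NELF mean ranged from 0.307 to 0.332 and the SOSS mean from 0.291 to 0.378, the highest without INIP (exact permutation p = 0.00833). Genes ranged from 72 to 102 and regions from 7 to 12. The NELF excess ranged from 9.88 to 13.6 percentage points within 5 kb of starts and from 11.9 to 15.05 within 1 kb. The log2 difference at histone genes ranged from 2.90 to 3.35.

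The 14 genes that the naming rule picked for their change kept their sign in all 224 alternative fits and their side of the threshold in 206. Luzp1 and the 10 higher genes kept it in all of theirs. The size of their folds depended on the pseudocount and on library size. On the log2 scale Hist1h4h, at 4.35, had 3.569 with a pseudocount of 4, 4.846 with 0.25 and 5.213 with thinned libraries. Hist1h2af went from 4.169 to 3.486 with a pseudocount of 4 and 5.216 thinned, Hist1h3g from 4.149 to 3.464 and 5.186, and Gm11335 from 4.275 to 3.461 and 5.001. Hist1h4b, at 4.339, had 3.384 with quantile-normalised values and 5.070 with a pseudocount of 0.25. Luzp1, at −3.373, had −2.293 with a pseudocount of 4 and −4.404 with 0.25. The U1 copy lost it in 11 fits: without a filter, with voom weights, thinned, and without each of NELFA, NELFB, NELFE, INIP, INTS11, INTS3, NABP1 and NABP2 (limma adjusted p up to 0.938). The other losses were in genes lower in NELF that are not described here. In simulated counts limma recovered 18% of genes changed 2-fold and 98% of those changed 4-fold, and depth and spread were not varied.

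At snRNA copies the NELF mean minus the Integrator mean within 5 kb was 0.013 times uniform with all 10 libraries (exact permutation p = 1.0), and with a library left out it ranged from −2.3794 without INTS9 (exact permutation p = 0.659) to 2.743 without INIP (exact permutation p = 0.579). A sign change around a difference near 0 has no direction. In the 1 kb downstream the difference ranged from 43.2 without NELFA (exact permutation p = 0.548) to 96.3 without INIP, and the share downstream from 29.6 percentage points without INTS3 (exact permutation p = 0.0635) to 43.5 without INIP. The share, at an exact permutation p of 0.0333 with all 10, had a p above 0.05 with any library other than INIP or NABP2 left out, of 0.0595 to 0.0952.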

Other observations

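The tests of snRNA copies, of position along genes, of histone genes by chromosome and by place, of local GC content, of sites with a first number of at least 10, of unique sequence, of 1 site per 100 bases, of sequencing runs and of fragment ends were chosen after the data had been seen, and the counts of other splits were planned.

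Copies of the U1 and U2 snRNA genes, whose transcripts Integrator cleaves at their 3′ ends, carried sites of both families. Within 5 kb of the 18 copies the density was 28.3 ± 4.68 times uniform in NELF and 28.3 ± 10.4 in Integrator, with 16.1 in SPT5 (exact two-sided permutation p = 1.0, adjusted p = 1.0 over 28 tests). Within 1 kb it was 67.1 ± 20.1, 47.1 ± 41.9 and 33.5 (exact permutation p = 0.405, adjusted p = 0.493). Of the sites in both 1-kb flanks, 88.0% ± 8.06 of NELF, 53.1% ± 24.5 of Integrator and 36.6% of SPT5 were downstream of the copy (exact permutation p = 0.0333, adjusted p = 0.0519, which did not pass). NELFE had all of its 20 there and INIP 47 of 49, while INTS3 had 26.7% and NABP1 35.6%. Density downstream was 128 ± 39.5 in NELF, 71.5 ± 98.4 in Integrator and 25.96 in SPT5 (exact permutation p = 0.324, adjusted p = 0.412), and upstream 17.1 ± 13.5, 30.6 ± 13.4 and 45.0 (exact permutation p = 0.176, adjusted p = 0.235). The Integrator mean downstream rested on INIP, at 267.9, with 11.8 to 67.6 in the other 5. Without INIP that mean was 32.2 ± 22.9 (SD, n = 5), below each NELF library, of which the lowest had 82.6 (exact permutation p = 0.00794 over 126 splits, adjusted p = 0.198 over 50 tests with a library left out). The share downstream was then 44.6% ± 14.3 in Integrator (exact permutation p = 0.00794, adjusted p = 0.198). Within 1 kb the Integrator mean was then 30.8 ± 13.8 (exact permutation p = 0.0238, adjusted p = 0.289). These differences did not pass after adjustment, and INIP was set apart after its values had been seen.

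Histone genes on each of 5 chromosomes held more NELF than Integrator sites, with an exact permutation p of 0.0048 (adjusted p = 0.009 over the same 28 tests) for each. Many of these 28 tests measured the same histone or gene-start sites in different ways, which lowers the adjusted p. Over the 11 lists fixed beforehand the histone list had an adjusted p of 0.0524 in the exact permutation test. On chromosome 13 (56 genes) the density was 122 ± 27.2 times uniform in NELF and 12.3 ± 6.19 in Integrator, on chromosome 3 (10 genes) 120.0 ± 42.4 and 26.1 ± 12.3, and on chromosome 11 (3 genes) 131 ± 34.5 and 14.3 ± 9.91. Hist4h4 on chromosome 6 had 109 ± 73.4 and 7.30 ± 6.55, and H2afx on chromosome 9 had 84.0 ± 8.11 and 20.8 ± 13.1. Around 68 protein-coding histone genes, NELF had 237 ± 93.6 in the 1 kb upstream, 134 ± 40.8 inside and 251 ± 81.3 in the 1 kb downstream, against 17.7 ± 9.68, 17.9 ± 8.17 and 29.1 ± 18.6 in Integrator. Flanks of neighbouring histone genes overlap. Along the 9710 genes of at least 20 kb, 26.2% ± 3.51 of NELF and 19.7% ± 3.60 of Integrator sites lay in the first 10% of the length (exact permutation p = 0.0286, adjusted p = 0.0471), with 34.1% for SPT5. In the next 10% Integrator held more, 12.3% ± 2.09 against 9.35% ± 0.558 (exact permutation p = 0.019, adjusted p = 0.0332). Strand preference did not differ beyond the spread, with 50.5% ± 0.466 of NELF and 50.7% ± 0.698 of Integrator sites on the strand of the gene (exact permutation p = 0.648, adjusted p = 0.725).

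NELF libraries held 12.97 percentage points more of their sites within 1 kb of gene starts than Integrator libraries. NELF sites also had a higher local GC content, 46.4% ± 0.972 against 44.2% ± 0.504, yet with every library weighted to the same GC distribution the difference was 8.80 points (17.1% ± 2.39 against 8.29% ± 1.33, exact permutation p = 0.0048, adjusted p = 0.009), which argues against GC content as the whole cause. Among sites with a first number of at least 10 the difference was 12.9 points, which argues against sites with little support. Runs of the same protein differed by at most 1.31 points, below the smallest gap of 4.89 between a NELF and an Integrator library, and SPT5 from another run lay above all 6 Integrator libraries; this met the bound set beforehand against the sequencing run, but the bound was insufficient because the NELF run held 0 Integrator libraries, so run and family cannot be told apart. Binding of NELF beside paused polymerase may account for the pattern and stays open as an untested hypothesis. NELF and Integrator libraries sequenced in the same run would separate run from family but would not test this binding.

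NELF libraries held more sites at histone genes, a log2 ratio of the mean folds of 3.04. Sites whose 35 genome bases are unique made up 95.8% of those at histone genes and 97.8% of 5000 sites drawn from all. Among them the ratio was 3.01, which argues against reads shared between copies identical over 35 bases as the cause. A copy that differs by 1 base counts as another sequence, so near-identical copies were not tested. With 1 site counted per 100 bases it was 2.85, which argues against a few positions recovered again and again. Runs of the same protein differed by at most 1.38-fold, and the smallest ratio between a NELF and an Integrator library was 3.82, but the NELF run held 0 Integrator libraries, so run and family cannot be told apart here either. A role of NELF at histone genes is a candidate explanation that was not tested and stays open. Repeats of NELF and Integrator fusions within a run would separate run from family but would not test that role.

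Pooled over the 55 pairs of libraries, identical positions were 12.1 times as frequent as positions at each offset of 1 to 20 bases. By pair the ratio ranged from 6.54 for NELFA with NELFE to 45.9 for INIP with INTS11, the latter from 31 identical positions. INIP with NABP2 had 44.2 and the other INIP pairs 12.6 to 27.2. Carry-over was not tested for the INIP pairs alone. In the pair that shared a lane, NABP1 with NABP2, the ratio was 13.4 (95% exact interval 11.7 to 15.1), and in other runs of these proteins it was 11.8 (8.34 to 16.3), which argues against carry-over within that lane as the cause. Of the 5274 distinct identical positions, 98.5% had unique sequence over 35 bases, which argues against sequence repeated without change over those bases. The other shares and ratios here count a position once for each pair of libraries. Fragments ended at the same base in 2.05% of identical positions (1.72 to 2.42) and in 0.692% of positions 1 to 20 bases apart (0.585 to 0.811), just under the bound of 3 times set beforehand for carried-over DNA, so a contribution of carry-over may remain and was not decided. Local sequence preference of the integrase, which would place integrations in different cells at the same base, was not tested and stays open.

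Pairs of libraries of different families from the same run had a mean correlation of 0.304 over 2 pairs, and the 65 pairs of different families from different runs had 0.269. Pairs of different proteins of the same family had 0.283 over 11 pairs from the same run and 0.293 over 10 pairs from different runs, so within families the mean was not higher for the same run. Different runs of the same protein had 0.319 over 3 pairs (range 0.249 to 0.366), within the spread of pairs of different proteins. All 6 NELF pairs were from the same run, and with 2 pairs of different families from the same run the effect of runs stays open.

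Of the splits of the 10 libraries into 4 and 6, 100 were examined, the real split included. In 3 of 100 limma gave at least the 90 genes of NELF against Integrator, and in 2 of 100 at least the 10 regions. Both shares lay under the limit of 0.05 set beforehand. Other splits gave more genes and more regions than the real one, so the counts do not single out the families and chance was not excluded. The highest other split gave 101 genes (INIP, INTS11, INTS9 and NABP1 against the rest), and another gave 100 (INIP, INTS11, INTS3 and INTS9); both keep the 4 NELF libraries together with 2 Integrator libraries. The highest other split for regions, NELFE, INIP, INTS11 and INTS9 against the rest, gave 76, several times the real count, which points to a structure of the samples beyond the families. None of these sets was a sequencing run.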
